A study of Mus musculus with 2 samples.

How the data were processed

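Total RNA from the chromatin fraction of C57BL/6J mouse bone marrow-derived macrophages, depleted of ribosomal RNA, was sequenced after the cells had been stimulated for 75 min with lipid A at 100 ng/ml, per the labels. Lipid A is the part of lipopolysaccharide that engages Toll-like receptor 4 (TLR4), and RNA on chromatin is enriched for transcripts still being made or processed. The series holds 2 libraries in 1 group, labelled as biological replicates 1 and 2. The labels give both the same donor, and whether the cultures came from separate mice is not given in the sources used here, so every SD and the biological coefficient of variation may describe cultures rather than animals. Replicate 1 was made from 250 ng of RNA and replicate 2 from 500 ng, with fragments of 250 to 400 bases, per the labels. No untreated cells, other time point or other cell fraction was analysed here, so no contrast between conditions was fitted.

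For each library the authors deposited a table of estimated (expected) counts, TPM (transcript counts scaled by length and by the table's total) and FPKM (fragments scaled by length and by depth) per gene and another per transcript, both derived from a transcriptome alignment to mm10 with GENCODE M21 annotation, per the deposited text that goes with each library. The column names are those RSEM writes; the aligner, quantifier and versions are not given in the sources used here. The same columns include the posterior standard deviation of each estimated count, a deposited value that was not used for any result. A further transcript table of estimated counts and TPM per library was derived by the authors directly from the reads and a transcript index of the same annotation, per the deposited text; its column names are those kallisto writes, and it is called the second quantification. Whether either quantification used strand is not given in the sources used here, so a gene and an antisense partner may share reads. TPM keeps no sequencing depth and is relative to everything else in the table: short RNAs with small effective lengths took a large part of it here.

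All 55536 annotated gene identifiers in the gene tables matched the GENCODE M21 annotation, which gave symbols, gene types and mm10 coordinates. A further 26248 rows with numeric identifiers, 96 spike-in sequences and 1 phiX174 sequence were not matched to genes here and were left out of library sizes and tests; together they held 0.409% of estimated counts in replicate 1 and 0.277% in replicate 2. The annotated genes held 21453617 counts in replicate 1 and 29638814 in replicate 2, and 3 counts corresponded to 0.140 and 0.101 CPM. Shares of counts are given with exact (Clopper-Pearson) 95% binomial intervals. The libraries carry no molecular identifiers in these tables, so intervals and floors cover counting error only. Where several annotated genes shared a symbol of a fixed list (such as Rmrp), their values were summed.

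A gene was taken as expressed at a TPM of 1 or more in both replicates. Before the data were examined, 23 gene lists were fixed, and 1 of the nuclear lncRNA list's 30 symbols had no match in the annotation. The level of a list was the median of log2(TPM + 1), set as a percentile among 10000 random lists of the same size drawn from the same class (protein-coding or other) and the same 10 bins of effective length. Where a level was set against expressed genes, the list was also cut to its members expressed in both replicates. The difference of a list between the replicates was its median log2 ratio of TPM + 1, replicate 2 over replicate 1, set among 10000 lists matched on class and on 10 bins of mean log2(TPM + 1). A pseudocount of 1 understates the change of low genes. A list was described as standing apart above the percentile 97.5 or below 2.5. These percentiles describe the 2 libraries, since genes are not replicates, and no p-value was attached to them. The retained intron share was the percent of a gene's transcript TPM on transcripts annotated as retained_intron.

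Expected counts were rounded and compared between the libraries gene by gene with an exact two-sided binomial test at the TMM-scaled share (edgeR 4.0.16, R 4.3.3), for genes with a summed count of 20 or more, with Benjamini-Hochberg adjustment at 0.05 and a fold of 2 or more. That test compares 2 libraries, not conditions. TMM factors were 0.810 and 1.24. The common dispersion came from edgeR with an intercept only. A chi-square of the rounded counts gave 489 per degree of freedom over 14441 degrees of freedom, so the tables were not copies of a single library. On counts simulated for 14475 genes with Poisson counting error only, 200 of 200 genes changed 4-fold were recovered and 1 unchanged gene was called. No variation between libraries was simulated, so this gives no error rate for the calls in the real libraries. There, 7307 of the tested genes (50.6%) had an adjusted p under 0.05 by the binomial test at any fold. In simulated values independent between genes, a list of 40 genes raised by 1 on the log2 scale lay at the percentile 100. Of 40 simulated lists with no shift, 4 lay outside the central 95%; that count was checked again with 200 lists, of which 9 did. GC content and length were transcript values from the GENCODE M21 sequences weighted by TPM.

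Genes named in the text followed a rule fixed before the data were examined. It took the 6 members of each list with the highest mean TPM, a fixed set of 15 response and identity genes, and list members under a TPM of 1 in both replicates. It also took the 20 nuclear protein-coding genes and 10 genes of other types with the highest mean TPM, the 5 genes in each direction with the largest fold between replicates at 100 or more counts in both, and the 10 list genes with the largest retained intron share at a TPM of 10 or more. Other genes are said to have been chosen after their values were seen. Alternatives covered pseudocounts, filters, FPKM, the second quantification, rescaling over nuclear protein-coding genes, DESeq2 1.42.0 size factors, library size only, and leaving out each replicate. Removing the trend on GC content and length, an expressed protein-coding background, and gene counts over expressed protein-coding genes, were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.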

Results

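Chromatin-associated RNA was measured in bone marrow-derived macrophages, cells grown from C57BL/6J mouse marrow, after 75 min with lipid A at 100 ng/ml, a ligand of TLR4. The series has 1 group with 2 libraries labelled as biological replicates. Both carry the same donor label, and whether the cultures came from separate mice is not given. The SD may therefore reflect cultures rather than animals. Replicate 1 held 21453617 estimated counts on annotated genes and replicate 2 held 29638814. Of 55536 annotated genes, 9645 had a TPM of 1 or more in both replicates; 7633 of these were protein-coding, 160 were lincRNAs and 372 were antisense genes. Values are means ± SD of the replicates (n = 2) in TPM on all annotated sequence unless stated, and positions are on mm10. Expressed protein-coding genes had a median ratio of TPM + 1 of 1.59, replicate 2 over replicate 1. The added 1 lowers this ratio for genes of low TPM. Each SD therefore mixes a shift between the libraries with the gene's own difference. Relative to the ratio of 1.59, and also on TPM + 1, Csf1r (43.2 ± 3.46 TPM) was at 0.562-fold and Nfkb1 (475 ± 203 TPM) at 1.17-fold. A small SD is therefore not a sign of a steady gene. The first question was which parts of the TLR4 response were present on chromatin at this time, described by level only, since no untreated library was analysed here.

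NF-kB target genes were among the most abundant protein-coding transcripts on chromatin. The median of the 35 genes of the NF-kB primary response list was 134 ± 62.8 TPM, and 34 were expressed; only Gpr84 was under 1 TPM in both. The highest was Tnfaip2 (chromosome 12, 111442469 to 111455018, plus strand), at 1855 ± 505 TPM. Malt1, a signalling protease, followed at 970 ± 636 TPM. Tnfaip3 (A20, an inhibitor of NF-kB signalling; chromosome 10, 19000910 to 19015657, minus strand) stood at 647 ± 355 TPM, and Nfkb1 at 475 ± 203 TPM. The cytokine gene Il1b was at 402 ± 115 TPM, the adhesion molecule gene Icam1 at 377 ± 136 TPM, Nfkbia, which encodes the inhibitor IkBa, at 345 ± 130 TPM, and Tnf at 321 ± 191 TPM. Among all nuclear protein-coding genes, the highest mean TPM belonged to the leukocyte immunoglobulin-like receptor genes Lilr4b (2452 ± 1362 TPM) and Lilrb4a (2257 ± 1383 TPM), which are close paralogs, so the split of reads between them is uncertain. Ahnak (1085 ± 161 TPM), Zeb2 (1055 ± 659 TPM), Cd44 (887 ± 602 TPM) and Fchsd2 (878 ± 666 TPM) were also among the 20 highest.

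Immediate early genes were lower, and unequal. The median of the 29 genes was 7.85 ± 0.679 TPM, with 25 expressed. Dusp1, a phosphatase of MAP kinases, was at 224 ± 139 TPM, the kinase gene Pim1 at 198 ± 68.6 TPM, Gadd45b at 156 ± 47.5 TPM and Klf6 at 139 ± 76.8 TPM. In contrast, Fos was at 6.82 ± 2.14 TPM and Egr1 at 1.34 and 1.66 TPM in replicates 1 and 2, while Fosb, Fosl1, Egr3 and Nr4a2 were under 1 TPM in both replicates. Against length-matched genes of any level the list lay at the percentile 100, as did the NF-kB list. With the immediate early list cut to its 25 expressed members and set against expressed genes only, it lay at the percentile 64.7.

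Most genes of the interferon and late lists were also present on chromatin. The 40 genes of the interferon and IRF response list had a median of 48.7 ± 38.7 TPM, with 36 expressed and with Cxcl9 and Tnfsf10 under 1 TPM in both. Ifnb1, which encodes interferon beta, was at 41.9 ± 44.4 TPM. Its highest members were the antiviral gene Rsad2 (702 ± 741 TPM), the RNA sensor gene Ifih1 (602 ± 597 TPM), Parp14 (584 ± 384 TPM), Gbp5 (416 ± 301 TPM), the chemokine gene Ccl5 (360 ± 267 TPM) and Oasl2 (343 ± 317 TPM). Of 26 late or secondary genes, 19 were expressed, with a median of 8.25 ± 6.56 TPM. The chemokine genes Ccl2 (232 ± 177 TPM) and Ccl7 (169 ± 137 TPM) led that list, followed by the complement gene C3 (99.3 ± 10.8 TPM) and the interleukin gene Il12b (55.7 ± 45.8 TPM). Il6 (7.75 ± 8.44 TPM) and Nos2 (3.48 ± 1.83 TPM) were far lower, and Il12a, Csf3, Cfb, Fpr1 and Ptx3 were under 1 TPM in both. Both lists lay at the percentile 100. The 19 expressed late genes lay at 92.0 against expressed genes.

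Feedback regulators, receptor components and macrophage genes were expressed together. Of 26 negative feedback genes 23 were expressed, with a median of 19.9 ± 11.7 TPM, led by Tnip3 (396 ± 305 TPM), Sqstm1 (350 ± 8.22 TPM), Cd274, which encodes PD-L1 (137 ± 111 TPM), and Socs3 (127 ± 72.4 TPM). Il10, an anti-inflammatory cytokine gene, was at 52.4 ± 40.3 TPM. Of 32 TLR4 pathway genes 30 were expressed, with a median of 17.9 ± 6.58 TPM; the kinase gene Ikbke was highest (643 ± 57.8 TPM), Cd14 was at 92.6 ± 34.8 TPM and Tlr4 itself at 3.43 ± 2.82 TPM. The macrophage identity list had 33 of 38 genes expressed, at a median of 24.1 ± 9.34 TPM, led by Gpnmb (913 ± 511 TPM) and Sirpa (340 ± 88.3 TPM). Csf1r was at 43.2 ± 3.46 TPM and the lineage factor gene Spi1 at 18.8 ± 0.919 TPM, while Lyz1, Cebpa, Cx3cr1 and Ccr2 were under 1 TPM in both. Of 17 alternative activation genes 6 were expressed, Stab1 (242 ± 132 TPM) and Mrc1 (158 ± 46.9 TPM) being the highest, and Arg1, Chil3 and Retnla were under 1 TPM in both. The feedback, TLR4 pathway and macrophage identity lists lay at the percentile 100 of length-matched lists of any level, and the alternative activation list at 71.5. The housekeeping list also lay at 100, so that position is not particular to the response. The lists were also cut to their expressed members and set against expressed genes only. The feedback and macrophage identity lists then lay at 100, TLR4 pathway at 99.95, housekeeping at 99.5 and alternative activation (6 genes) at 29.4.

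**Figure D1:**
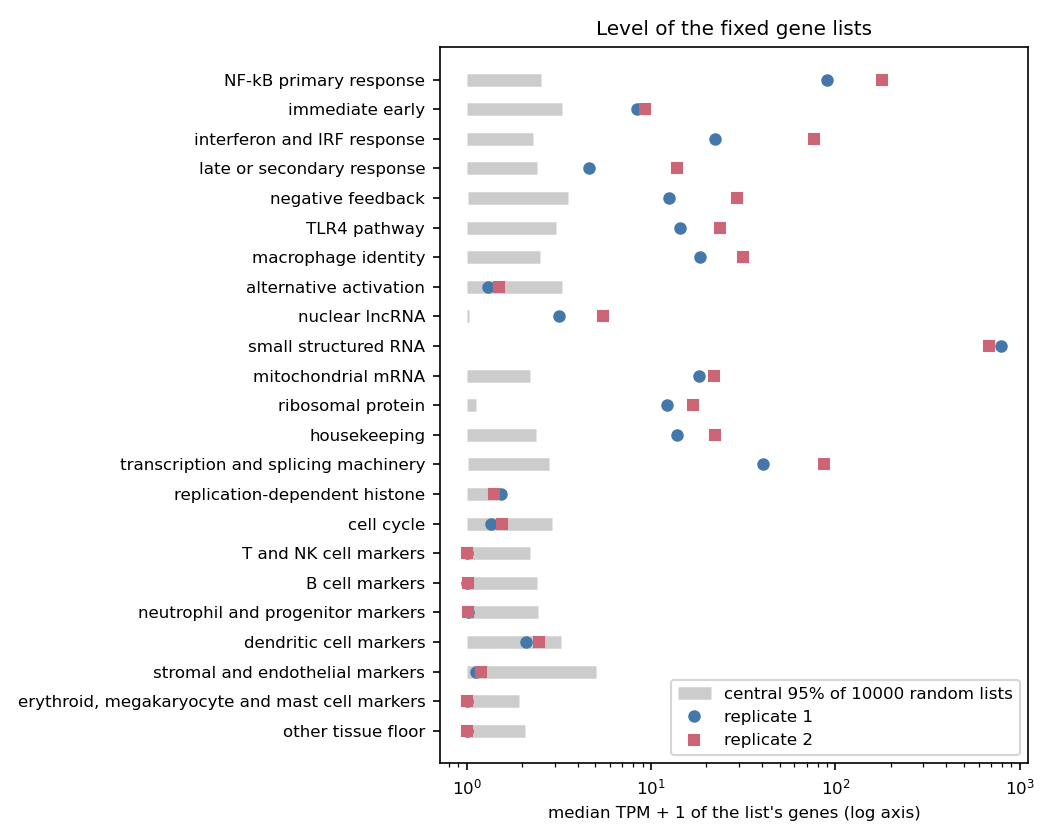
Median TPM + 1 (log axis) of each fixed gene list in replicate 1 (circles) and replicate 2 (squares); grey bars span the central 95% of 10000 length-matched random lists for the mean of both replicates, and nearly vanish where such lists are close to 0. The NF-kB list sits at 89.2 and 178 TPM, and the other tissue floor at 0 in both.

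**Figure D2:**
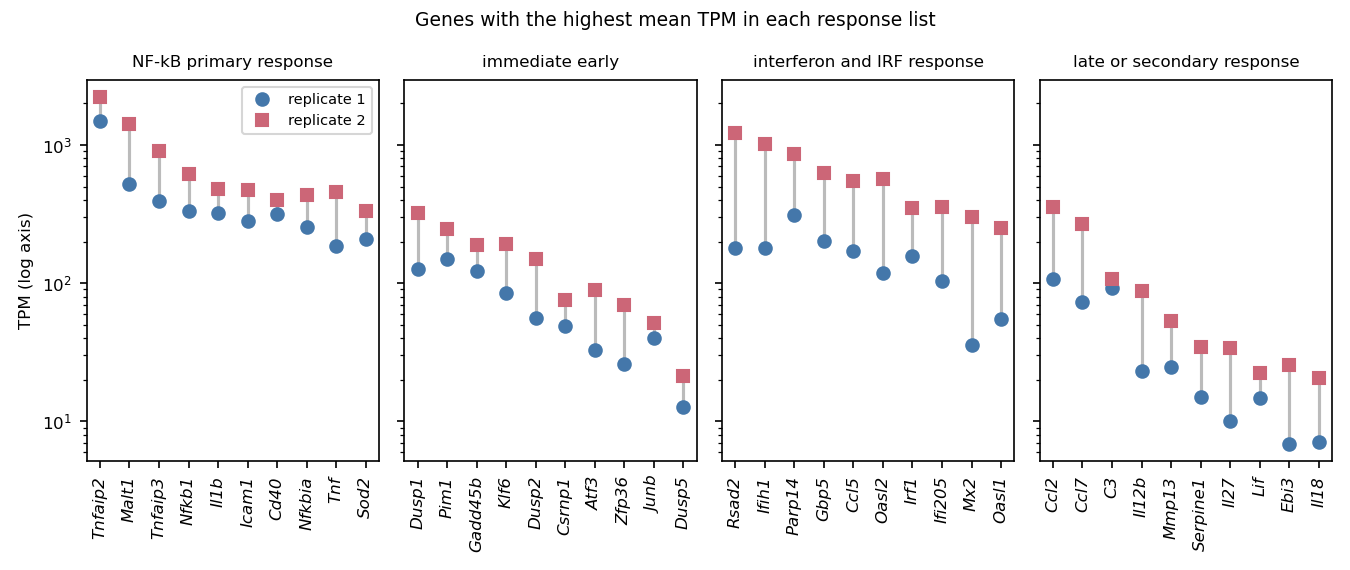
TPM (log axis) of the 10 genes with the highest mean TPM in each of 4 response lists, with a grey line joining replicate 1 (circles) and replicate 2 (squares). The gap between the replicates is wide for interferon genes such as Rsad2 (179 and 1226 TPM) and narrow for Tnfaip2 (1498 and 2211 TPM).

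Most markers of other cell types and of proliferation were under 1 TPM. In the first quantification, none of 16 B cell genes, of 17 stromal and endothelial genes or of 30 genes typical of other tissues was expressed in both replicates. Of the other marker lists, 2 of 22 T and NK cell genes were expressed (Il7r at 14.9 ± 4.06 TPM and Cd28 at 5.16 ± 4.03 TPM), 1 of 20 neutrophil and progenitor genes (Csf3r at 21.7 ± 5.59 TPM) and 3 of 20 erythroid, megakaryocyte and mast cell genes (Pf4 at 3.69 ± 0.0141 TPM). Of 18 dendritic cell genes 9 were expressed, led by the transcription factor gene Tcf4 (108 ± 67.8 TPM); Cd74 was at 5.68 ± 0.127 TPM, and Xcr1, Clec9a, Siglech and Cd209a were under 1 TPM in both. Of 29 cell cycle genes 4 were expressed and of 30 replication-dependent histone genes 5, with medians of 0.450 ± 0.141 and 0.472 ± 0.103 TPM. The marker lists lay between the percentiles 5.04 and 91.2 of length-matched lists: 7.32 (T and NK cell), 24.2 (B cell), 34.0 (neutrophil and progenitor), 91.2 (dendritic cell), 36.2 (stromal and endothelial), 41.1 (erythroid, megakaryocyte and mast cell) and 5.04 (other tissue). The cell cycle list lay at 70.9 and the histone list at 98.4, which was 73.76 with the second quantification. The 5 expressed histone genes alone lay at 2.56 against expressed genes. Counts of expressed genes in this paragraph hold for the first quantification only. Over all genes the second put 16112 at 1 TPM or more, against 9645 in the first, among them the T cell gene Cd3d (13.0 and 28.8 TPM).

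Malat1 and the ribosomal DNA locus held large and unequal shares of counts. The nuclear lncRNA Malat1 (chromosome 19, 5795690 to 5802672, minus strand) held 4.45% (95% interval 4.44 to 4.45%) of counts in replicate 1 and 10.8% (10.8 to 10.8%) in replicate 2. Neat1, the scaffold RNA of paraspeckles, was at 1348 ± 249 TPM, Xist at 924 ± 462 TPM, the miR-155 host transcript Mir155hg at 260 ± 272 TPM and Firre at 108 ± 12.8 TPM. The ribosomal DNA locus on chromosome 17, a group chosen after its values were seen, held 41.6% of counts in replicate 1 (interval 41.6 to 41.6%) and 12.7% in replicate 2 (12.7 to 12.7%). It comprises Gm26917 (39843013 to 39846341, plus strand), Gm42418 (39846958 to 39848788, plus strand) and the rRNA gene CT010467.1 (39846353 to 39848827, minus strand). CT010467.1 spans all 1849 bases of the RefSeq pseudogene Rn18s-rs5, an 18S ribosomal RNA copy, and Gm42418 overlaps 1245 of them. Gm26917, which overlaps 0 of them, held most of the share: 35.1% of counts in replicate 1 (interval 35.1 to 35.2%) and 10.8% in replicate 2 (10.8 to 10.8%). Protein-coding genes held 47.0% and 66.2% of counts, and 19.5 ± 7.77% of TPM. Genes annotated as snoRNA or scaRNA held 42.3 ± 4.36% of TPM but 0.532 ± 0.171% of counts, and 7.81% of TPM in the second quantification. The mitochondrial chromosome held 0.0362 ± 0.00463% of counts, which leaves out any of its reads placed on nuclear copies. In its list mt-Co1 was highest (132 ± 6.14 TPM) and mt-Co2, a gene that has near-identical nuclear copies, was listed at 0, against 22.6 and 29.8 TPM in the second quantification. Likewise, mt-Co3 was at 0.03 and 3.43 TPM, against 44.0 and 42.4 in the second. All 66 ribosomal protein genes were expressed, at a median of 13.6 ± 3.22 TPM, led by Rpl23 (60.7 ± 9.19 TPM), as were all 38 genes of transcription and splicing (62.5 ± 32.8 TPM), led by Rbm39 (670 ± 268 TPM), and all 30 housekeeping genes (17.0 ± 5.93 TPM), led by Actb (197 ± 64.3 TPM). Among small structured RNAs, Rmrp, the RNA of RNase MRP, summed over the annotated genes of that symbol, was highest (105637 ± 40579 TPM), and Rn7sk, which holds the elongation factor P-TEFb, was at 8918 ± 4293 TPM. The list medians were 738 ± 78.3 TPM for small structured RNAs (17 of 25 expressed), 3.34 ± 1.67 TPM for nuclear lncRNAs (17 of 29) and 19.2 ± 2.69 TPM for mitochondrial mRNAs (8 of 13), and all 6 lists of this paragraph lay at the percentile 100.

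**Figure D3:**
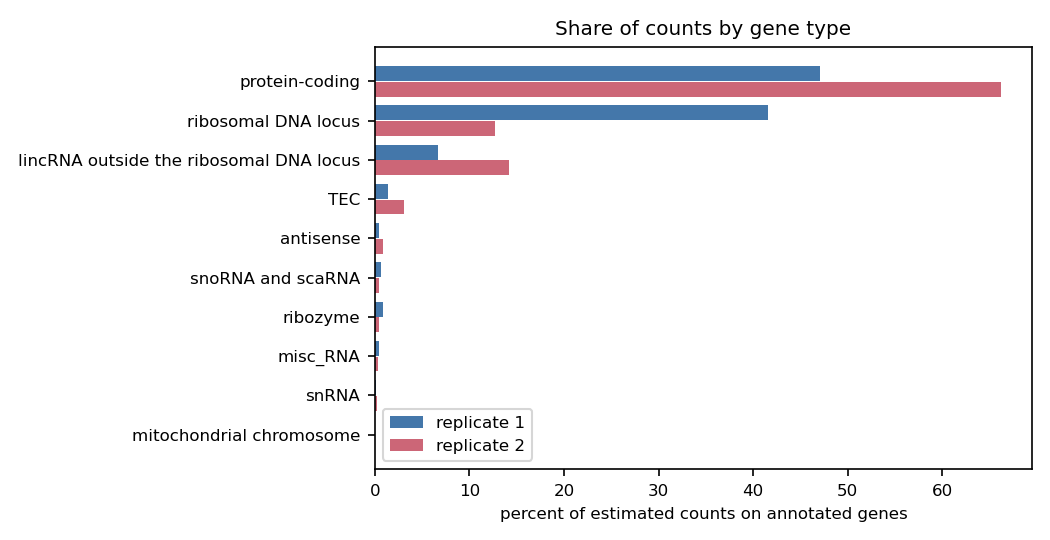
Percent of estimated counts on annotated genes (bars from 0) by gene type in replicate 1 and replicate 2. The ribosomal DNA locus holds 41.6% of counts in replicate 1 and 12.7% in replicate 2, and protein-coding genes 47.0% and 66.2%.

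Transcripts annotated with a retained intron made up 37.8 ± 1.84% of the transcript TPM of protein-coding genes, 24.1 ± 3.39% of their expected counts and 32.9 ± 1.37% of their TPM in the second quantification. Chromatin-bound RNA includes transcripts that are not yet spliced, so this share cannot tell a retained intron from one not yet removed. Lists were matched on expression only, not on the number or length of such transcripts. Over 5230 expressed genes with such a transcript the median share was 45.9%, with quartiles of 29.4% and 62.5%. Ribosomal protein genes had the highest list position, with a median share of 60.6% over 54 genes, at the percentile 100 of expression-matched lists; Rpl5 stood at 94.2%, Rpl3 at 93.0% and Rpl10a at 92.7%. Interferon genes had a median of 62.9% over 23 genes (percentile 99.2), which was inside the central range with counts (84.36) or with the second quantification (90.09). NF-kB genes had a median of 56.3% over 21 genes (percentile 89.5) and immediate early genes 28.9% over 6 genes (percentile 3.59). The NF-kB list was above the central range with counts (98.37). The immediate early list was below it without replicate 1 (1.36) and inside it without replicate 2 (11.06). Within lists the share differed between genes: Dusp1 had 95.1% and Tnip3 94.6%, whereas Nfkbia had 9.73% and Pim1 7.16%. The alternative activation list, with 4 genes, had a median of 20.6% (percentile 2.12), which moved to 14.05 with the second quantification.

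Interferon genes were higher in replicate 2. TPM + 1 of expressed protein-coding genes was higher in replicate 2 by a median of 0.67 on the log2 scale (1.59-fold), and list differences are given against matched lists for that reason. All 40 interferon list genes had a higher TPM in replicate 2, with a median log2 ratio of 1.84 where matched lists had 0.75 (0.56 to 0.95), and 38 exceeded the protein-coding median. Ifit2 was at 13.3 and 174 TPM in replicates 1 and 2, Cxcl10 at 25.3 and 197, Rsad2 at 179 and 1226, Ifih1 at 180 and 1024, and Ifnb1 at 10.5 and 73.3. In the exact binomial test of TMM-scaled counts, 22 of 39 tested list genes were higher in replicate 2 and 0 lower, at 2-fold or more; adjusted over the list alone the counts were also 22 and 0. DESeq2 size factors also gave 22 and 0, and library size only gave 33 and 0. Late genes (median 0.92, percentile 99.6) and negative feedback genes (0.91, percentile 98.8) were also above matched lists, whereas NF-kB genes (0.89, percentile 82.5), immediate early genes (0.56, percentile 29.7) and macrophage identity genes (0.56, percentile 8.80) were not apart from them. With the second quantification the late list was inside the central range (96.47) and the immediate early list below it (0.55). In the binomial test 0 of 35 NF-kB genes differed at that fold, while library size only called 8 of them higher.

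Ribosomal protein genes and small structured RNAs lay on the other side. The 66 ribosomal protein genes had a median log2 ratio of 0.31 where matched lists had 0.75 (0.61 to 0.89), and on TMM-scaled counts their median was -0.40 relative to expressed protein-coding genes. Their ratio was above 0 in TPM and with library size only (0.09) and below 0 with TMM (-0.52), so its direction depended on the scaling, while the position relative to protein-coding genes is the same under any single factor by construction. Small structured RNAs had a median of -0.31 where matched lists had 0, and 12 of 16 tested were lower in replicate 2 and 0 higher; with library size only 7 were lower and 1 higher. On TMM-scaled counts their median was -1.35 relative to expressed protein-coding genes, where the interferon list had 1.31. With expressed members only the list lay at the percentile 3.59, inside the central range, against 0.05 with all members. On TMM-scaled counts, the 5 largest differences toward replicate 1 among genes with 100 or more counts in both libraries were all U3 snoRNA genes, Rnu3a (log2 ratio -3.13) and Rnu3b1 to Rnu3b4, which carry identical counts and cannot be told apart. On the same scale, the 5 largest toward replicate 2 were Ifit2 (2.73), Ifi209 (2.68), Ifi44 (2.61), Gm28048 (2.36) and Irgm2 (2.35). Stab1, a scavenger receptor gene, was at 335 and 148 TPM in replicates 1 and 2.

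With TMM scaling the calls adjusted over the list alone equalled those over all genes in every list. Macrophage identity had 0 of 37 tested genes higher in replicate 2 and 4 lower, TLR4 pathway 1 and 0 of 31, immediate early 1 and 1 of 28, late 2 and 0 of 23, feedback 2 and 0 of 25, and alternative activation 0 and 1 of 11. Ribosomal protein genes had 0 higher and 8 lower of 66 (1 and 0 with library size only), mitochondrial mRNAs 1 and 4 of 12, nuclear lncRNAs 3 and 1 of 21, housekeeping 0 and 2 of 30, and transcription and splicing 0 and 0 of 38. The mitochondrial gene called higher was mt-Co3, with 0.41 and 59.8 counts in replicates 1 and 2. In the second quantification it was at 44.0 and 42.4 TPM, so that call depended on the quantification. Histone genes had 0 higher and 4 lower of 16, cell cycle 1 and 1 of 19, dendritic cell 0 and 3 of 14, stromal and endothelial 0 and 1 of 10, T and NK cell 1 and 1 of 6, neutrophil and progenitor 0 and 0 of 3, erythroid, megakaryocyte and mast cell 0 and 1 of 2, and B cell 0 and 0 of 1. None of the other tissue genes had counts enough to be tested. With library size only, the genes higher and lower were 10 and 0 for late, 11 and 0 for feedback, 10 and 0 for TLR4 pathway, 10 and 0 for nuclear lncRNA and 7 and 0 for immediate early genes. They were 5 and 0 for macrophage identity, 2 and 1 for alternative activation, 1 and 3 for mitochondrial mRNA, 3 and 0 for housekeeping and 3 and 0 for transcription and splicing genes. They were 1 and 2 for histone, 5 and 0 for cell cycle, 4 and 0 for dendritic cell, 6 and 1 for stromal and endothelial, 2 and 0 for T and NK cell and 0 and 0 for neutrophil and progenitor genes. Median log2 ratios of TPM + 1 lay at the percentiles 1.42 (mitochondrial mRNA, 0.33), 17.6 (housekeeping, 0.65), 55.8 (transcription and splicing, 0.78), 71.0 (TLR4 pathway, 0.77), 61.3 (nuclear lncRNA, 0.36) and 73.1 (alternative activation, 0.16). The housekeeping list lay at 1.52 with the second quantification. With the GC and length trend removed, transcription and splicing lay at 1.38 and TLR4 pathway at 98.96. The cell cycle list (0.16, percentile 99.9) and the stromal and endothelial list (0.11, percentile 99.0) stood above matched lists at TPM values near 0. The cell cycle position turned to 0.01 with TMM rescaling, 28.73 with expressed members and 17.2 with the GC and length trend removed, and the stromal and endothelial position was 81.98 with the second quantification. The histone list (0.06) lay at 94.2, and at 0 with TMM rescaling. The dendritic cell list (0.11) lay at 9.67, and at 1.57 with the GC and length trend removed. The remaining marker lists had a median of 0.

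Over all genes the replicates correlated with a Pearson r of 0.933 and a Spearman rho of 0.910 across 12047 genes, which are not independent replicates; for protein-coding genes rho was 0.949. The biological coefficient of variation was 0.305. Of 14442 genes tested between the libraries, 985 were higher in replicate 2 and 700 lower by the exact binomial test with Benjamini-Hochberg adjustment and a fold of 2; with library size only these counts were 3805 and 128. Of these genes, 466 of the higher and 532 of the lower were protein-coding, and tested alone protein-coding genes gave 471 higher and 533 lower. The log2 ratio followed GC content, with a Spearman rho of -0.55 across 7619 expressed protein-coding genes: the 1524 genes with the lowest GC (median 42.1%) had a median of 1.05, and the 1524 with the highest (57.4%) had 0.31. Of the 7615 tested genes among these, 228 were higher and 307 lower; with the trend on GC content and length removed from the ratio, and the adjusted p left as it was, 207 were higher and 59 lower, and the interferon list had a median of 1.08. Both of these counts were added after seeing the data.

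**Figure D4:**
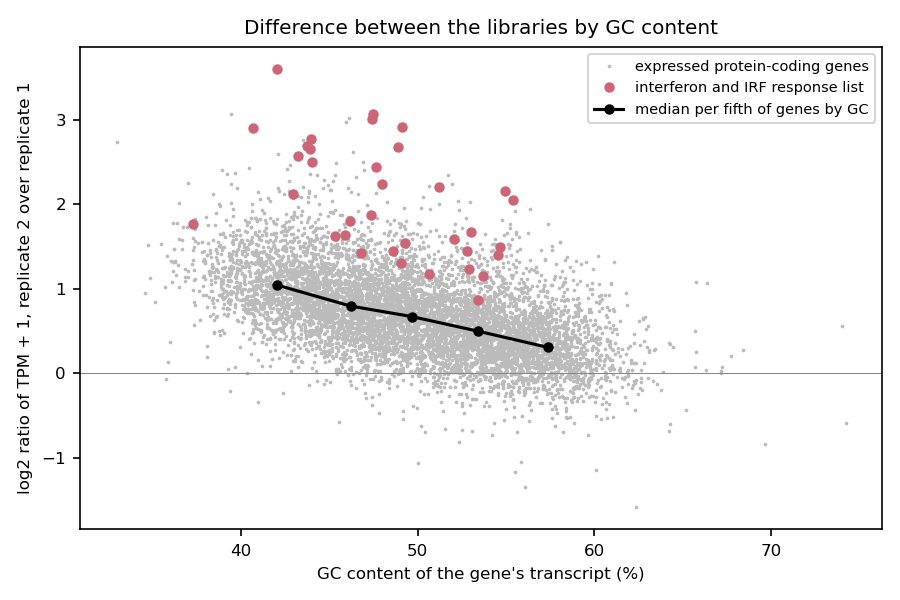
Log2 ratio of TPM + 1, replicate 2 over replicate 1, against the GC content (%) of each gene's transcripts, with 1 grey point per expressed protein-coding gene, red points for the interferon and IRF response list and black points for the medians of 5 equal groups of genes by GC. The black points fall from 1.05 to 0.31, and the interferon genes lie above them.

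The rank correlation between the quantifications was higher over protein-coding genes than over all genes. Across genes with a TPM of 1 or more in either, Spearman's rho was 0.567 in replicate 1 (16512 genes) and 0.557 in replicate 2 (20873 genes), and for protein-coding genes 0.870 and 0.835. Of 21123 genes, 2568 were at least 4-fold higher in the second quantification in both libraries and 68 at least 4-fold lower. The former included 562 miRNA genes, 517 protein-coding genes and 324 lincRNAs. Lgals3, a galectin gene, was at 149 and 306 TPM in the first quantification and at 1043 and 2119 in the second. Klf10, chosen after its values were seen, was at 2.73 and 2.57 TPM in the first and 89.7 and 177 in the second. The T cell gene Cd3d was at 0.02 and 0 in the first and at 13.0 and 28.8 in the second. Tnfaip2, Rsad2 and Ifnb1 were within 2-fold in both libraries.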

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

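The tests of library composition, of multigene families and of ribosomal RNA, the test of low counts and the look at starting amount were chosen after the values were seen; those of GC content and of overlapping genes were written down before.

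Sequences outside the genes analysed carried counts above the limit that a count of 0 allows. The phiX174 sequence, a common sequencing control, held 88174 estimated counts in replicate 1 and 82155 in replicate 2. Entries with a numeric identifier, which were not matched to genes here, held 5 estimated counts in replicate 1 and 34 in replicate 2. In the second quantification, spike-in sequences held 30 estimated counts in replicate 1 and 81 in replicate 2, all on 1 sequence in each library, while the first quantification gave 0 in both.

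The interferon and IRF response list was higher in replicate 2, with a median log2 ratio of TPM + 1 of 1.84. A factor common to all genes, from library composition or scaling, would move matched lists as much, so it alone does not set a list apart from them. The list lay at the percentile 100 among matched lists, and the NF-kB list (0.89) at 82.5. That position was known when the test was chosen, and a common factor cannot change it, so it adds no new support. Removing the trend on GC content and length left the list at the percentile 100, and its excess over matched lists was 1.05 before and 1.03 after, which argues against that trend as the whole cause. The 23 members outside the Ifit, Oas, Mx, Gbp, Ifi200 and Cxcl families had a median log2 ratio of 1.87 and again lay at the percentile 100, which argues against shared reads within those families as the whole cause. The starting RNA amount, the cultures, the timing of harvest and any batch were 1 per replicate and stay open, and no biological explanation was tested, since both libraries belong to 1 group.

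The ribosomal DNA locus on chromosome 17 took a larger share of counts in replicate 1. Ribosomal RNA left after depletion may contribute, but no test here decides it. Of the genes there annotated as lincRNAs, Gm42418 overlaps 1245 of the 1849 bases of the 18S copy Rn18s-rs5, and Gm26917 overlaps 0. Gm26917 and Gm42418 had log2 ratios on TMM-scaled counts of -2.31 and -2.14, the larger being -2.143, both below the 5th percentile of 381 other lincRNAs (-0.90). The annotated rRNA CT010467.1 went the same way, at -2.87. The genes were grouped because of this difference, so these values describe it and do not test its cause. Whether the smaller starting amount of RNA in replicate 1 contributed cannot be told apart from any other difference between the cultures or libraries, with 1 library per starting amount.

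Protein-coding genes far apart between the quantifications numbered 517, at least 4-fold higher in the second in both libraries. Of these, 31.3% overlapped the span of another expressed gene, against 42.7% of the other 11536, an odds ratio of 0.612 (95% interval 0.507 to 0.740, Fisher's exact test), so overlap was less frequent in the set. That argues against reads from an overlapping gene as the whole cause, although the compared genes were not matched on length or level. For the 162 genes of the set that do overlap, that cause stays open. The median second-quantification count of the 517 genes was 380.2 in replicate 1 and 949 in replicate 2, where the first quantification gave 3 and 5. The low first count was what low counts as a cause predicted and the high second count was what it forbade, and choosing genes higher in the second makes the first low, so low counts cannot be told apart from other causes. That reading replaced an earlier one, made with the values in view, that took the second count alone as deciding against low counts. Reads shared with repeats or with unspliced RNA were not tested and stay open.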

How the results depend on the processing

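No paired analysis was possible because the series has 1 group only. Of the alternatives, GC and length removal, the expressed protein-coding background and the gene counts over expressed protein-coding genes were chosen after seeing the data; where a value below moved, the cause was not tested. The interferon list stayed at the percentile 100 between replicates under every alternative run, and the ribosomal protein list at 0. Expressed genes numbered 4843 at a TPM of 5 and 16112 with the second quantification. Genes higher in replicate 2 numbered 3805 with library size only, 471 among protein-coding genes only, 228 among expressed protein-coding genes only and 207 among the latter with GC and length removed. Genes lower numbered 128 with library size only, 406 at a summed count of 100, 533 among protein-coding genes only, 307 among expressed protein-coding genes only and 59 among the latter with GC and length removed. List levels of the expressed members alone, against expressed genes, were 64.74 (immediate early) and 92.0 (late). They were 2.56 (histone, 5 genes, on the other side) and 0.18 (erythroid, megakaryocyte and mast cell, 3 genes). With the second quantification the levels of all members were 73.76 (histone) and 0.38 (other tissue floor). Leaving out a replicate put the histone list at 95.1 to 98.92. List differences with the second quantification were 0.55 (immediate early), 96.47 (late), 1.52 (housekeeping) and 81.98 (stromal and endothelial). With GC and length removed they were 98.96 (TLR4 pathway), 1.38 (transcription and splicing), 1.57 (dendritic cell) and 17.2 (cell cycle, from 99.86). The cell cycle list was also turned by TMM rescaling (0.01) and at 28.73 with expressed members or the expressed background, and its members are mostly near 0. TMM rescaling put the histone list at 0. Expressed members only gave 3.59 for small structured RNAs and 2.44 for erythroid, megakaryocyte and mast cell genes, which was also 2.44 with the expressed background. The retained intron position was 98.37 for NF-kB genes with counts, 84.36 and 90.09 for interferon genes with counts and the second quantification, and 4.86 and 14.05 for alternative activation genes. Leaving out a replicate gave 1.36 to 11.06 for immediate early and 1.27 to 4.05 for alternative activation genes. By expected counts the shares were 56.6% (protein-coding), 36.08% (lincRNA, which includes 2 genes of the ribosomal DNA locus; 10.4% outside it), 0.5317% (snoRNA and scaRNA), 27.16% (ribosomal DNA locus) and 0.03622% (mitochondrial chromosome). By the second quantification they were 30.29% (protein-coding), 7.806% (snoRNA and scaRNA) and 0.04087% (mitochondrial chromosome). Pearson's r between quantifications was 0.563 with a pseudocount of 0.1 and 0.806 with no filter, and Spearman's rho 0.744 with no filter. Of 185 named genes, 87 moved by more than the SD with the second quantification, and all 154 rescaled over nuclear protein-coding genes did. Rescaling multiplies all these genes of a library by 1 common factor, so the second count was fixed in advance and says nothing of single genes. With 2 replicates, a value such as 41.9 ± 44.4 TPM for Ifnb1 leaves its level open within several-fold.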

Other observations

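Xist, the RNA that coats the inactive X chromosome, was at 597 and 1251 TPM in replicates 1 and 2, from 199773 and 508008 counts. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, chosen after their values were seen, held 0 to 2 counts per library in the first quantification. The labels state that sex was not collected. In the second quantification these genes had TPM values of 2.21 and 7.70 for Kdm5d, 3.04 and 10.05 for Uty, 0.577 and 1.79 for Ddx3y, and 0.196 and 0.705 for Eif2s3y. Those values give a sense of how much signal the second quantification placed on genes for which the first held almost no reads.

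The proliferation marker Mki67 stood apart from the rest of the cell cycle list, at 53.3 ± 21.4 TPM (SD, n = 2), with Pcna, the replication clamp, at 23.9 ± 16.9. The mitotic genes Ccnb1, Cdk1, Plk1, Aurkb, Birc5 and Cdc20 were under 1 TPM in both libraries in the first quantification. In the second, Cdk1 was at 4.17 and 12.8 TPM, Birc5 at 2.74 and 8.58 and Aurkb at 0.968 and 2.99, while Ccnb1, Plk1 and Cdc20 stayed under 1.

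Some genes outside the fixed interferon list were picked because their TPM was higher in replicate 2, so their direction adds no support to that list. Irgm1 was at 4.28 and 40.6 TPM in replicates 1 and 2, Xaf1 at 8.81 and 50.9, Slfn9 at 3.12 and 20.1, Psmb9 at 2.11 and 11.7, and Cd86 at 17.6 and 103.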
